A study of Mus musculus with 12 samples.

How the data were processed

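The series holds 12 sequenced samples of mouse liver (C57BL/6, postnatal day 21): 3 immunoprecipitations with an antibody against m6A and 3 inputs for each of 2 genotypes, Bmal1 knockout and wild type. Per the labels' protocols, total RNA was extracted with TRIzol, polyadenylated RNA was purified, and immunoprecipitated fragments and input were made into cDNA and sequenced with standard Illumina libraries. The series' design text speaks of HepG2, a human liver cancer line, whereas every sample label gives mouse liver; the labels were followed, and the peak coordinates are of a mouse build. Groups and replicate numbers came from the sample labels. The 6 immunoprecipitated libraries have a deposited peak list each. The 6 inputs have none and were not analysed here.

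The submitters' processing notes name CASAVA 1.8.2, MACS 1.4.2 and the mouse build mm10 without giving their roles, and the peak identifiers carry the name of MACS. Peaks were listed per library, so replicates were not pooled. The aligner, the control used in calling, the duplicate handling and the filters are not given in the sources used here. The deposited read counts per peak (tags) are whole numbers that are not scaled to library size. The authors' score, per the file headers, is minus 10 times log10 of the peak's p-value; its lowest value in every list was 50, which corresponds to p = 1e-05. The authors' fold enrichment is a ratio of the peak over its background within 1 library. The authors' false discovery rate is in percent. Its relation to the score differed between lists, with a Spearman correlation across peaks from -0.98 to 0.97, so the rate was not used to rank peaks. Score, fold and rate were used only to describe, rank or filter peaks within a list, never to compare lists. The lists give peak length in bases, as deposited. Peak identifiers ran without gaps in each list.

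Coordinates are those of the lists, counted from 1, in build mm10. Gene positions came from an NCBI RefSeq gene table of the same assembly (GRCm38.p6) with 21900 protein-coding and 12727 long non-coding genes. It holds gene spans without exons, and no genome sequence was used here. The planned assignment of summits to exons was therefore replaced by the gene span: a gene has a peak when a peak summit lies between its start and end. A summit in an intron or in an overlapping gene counts too, and strand was not considered. The planned shares of summits per transcript part and with the m6A sequence motif were not computed.

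Peaks of all lists that overlapped by 1 base or more were merged into regions. A region or gene was called in 1 genotype only when it had a peak in 3 of 3 libraries of that genotype and in 0 of 3 of the other. No region or gene can pass a test of its own in such a design, so counts were tested as a whole. They were set against the other sets of 3 libraries and against 500 randomisations that keep the number of libraries of every region and the number of regions of every library (1000 for gene lists). Per-library values were compared by exact two-sided permutation over 20 label assignments (smallest p 0.1). The overlap of lists was compared by an exact one-sided permutation over the 10 splits. For 18 gene lists of 399 genes, of which 398 were found in the gene table, Fisher's exact two-sided test compared members called in 1 genotype only with all other genes that had a peak, with Benjamini-Hochberg adjustment over 36 tests and a threshold of 0.05. Members with a peak in all 6 libraries were tested likewise over 18 lists.

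The tests, gene lists and alternatives were fixed before the data were examined, except as said here. Added afterwards were the gene-end measure, the results without chromosomes X and Y, the test of gene lists against randomisations and the tests of explanations, some of them chosen only after their results were seen. The genes named are Arntl, 20 clock and m6A genes, every list member called in 1 genotype only (at most 12 per direction), the 10 genes per direction called in 1 genotype only with the highest median within-list percentile of the score, and the 10 genes with a peak in all 6 libraries with the highest percentile of fold. Other list members named as examples were chosen after their values were seen. Some list members count in the totals but are not reported here by name.

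Alternatives were a score of at least 100, a false discovery rate of at most 5%, a fold of at least 5, only the 3023 strongest peaks per list, leaving out each library, any overlap of a peak with a gene span, protein-coding genes only, and a stricter overlap. In the last, a reciprocal overlap of 50% replaced the Jaccard index and summits merged within 100 bases replaced the regions. The replicate number as a block was also tried. The merging and counting were tested on simulated lists of 8102 regions for the comparison of 3 wild-type and 3 knockout lists, with 200 regions planted per genotype. All 200 were recovered in each direction. Planted regions were set apart and placed in all 3 lists of a genotype, so their recovery checks the counting only. Among regions without a planted difference, 41 were in the wild-type lists only, against 56.8 ± 7.78 (SD) expected from randomisations. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.

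Depth can be read only as reads inside called peaks, which move with how much was called. A short list, such as that of knockout library 1, holds fewer genes whether or not the RNA differs, and no confidence interval for single genes can be formed from the lists.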

Results

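Sites of N6-methyladenosine (m6A), a methylation of adenosines inside messenger RNA, were mapped in mouse liver by immunoprecipitating fragments of polyadenylated RNA with an antibody against m6A and sequencing them. The samples came from C57BL/6 mice on postnatal day 21. Libraries of animals lacking Bmal1 (gene symbol Arntl), the transcription factor that pairs with CLOCK to drive the circadian clock, were compared with wild-type libraries. Each genotype had 3 immunoprecipitated libraries with 1 deposited peak list each, and the 6 matching input libraries were not analysed here. The comparison asks where the m6A signal called in liver differs when the clock lacks BMAL1, with hepatic lipid metabolism as the series' stated subject. The labels do not say that the 3 libraries of a genotype came from separate animals. The exact permutation p-values therefore measure the spread between these libraries, which may be technical. Fisher's exact tests, and tests against randomisations that keep list lengths, take genes or regions as units and measure no spread between libraries. The labels do not state the sex of the animals either, and the sample information used here holds no time of day of collection. A peak depends on how much of a transcript was present as well as on its methylation, and transcript levels were not analysed here. No library had a peak in Arntl itself (chromosome 7, 113178471 to 113314126, build mm10), so the lists offer no check of the knockout.

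Several clock-controlled genes were called in wild-type libraries alone. Dbp, Usp2 and Noct had a peak in all 3 wild-type libraries and in none of the 3 knockout libraries. Dbp encodes a clock-controlled transcription factor, Usp2 a deubiquitinase and Noct the rhythmic protein nocturnin. Per3 and Ciart had a peak in 3 wild-type libraries and 1 knockout library, and Bhlhe41 in 2 and none. Nr1d1, Tef and Hlf had a peak in 3 wild-type and 2 knockout libraries, and lacked one in knockout library 1, the shortest list. Of the 10440 genes with a peak, 1267 had one in 3 wild-type and 2 knockout libraries. Nr1d2, which encodes the repressor REV-ERBβ, had a peak in all 6. Npas2 was the reverse, with a peak in 2 knockout libraries and no wild-type library, while Clock and Cry1 each had a peak in 1 knockout library only. Per2 had a peak in 3 knockout and 2 wild-type libraries, Cry2 in 2 of each, and Per1 in none. All peaks assigned to Cry2 also lay in the span of D930015M05Rik, so none can be assigned to Cry2 alone. Peaks of Per2 fell in 7 regions, and the main one was called in 1 library of each genotype. A fraction of 0.4 of the Per2 peaks also lay in the span of another gene, Gm35591 at the main region.

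The strongest wild-type region of Dbp spanned 45704797 to 45709032 on chromosome 7, over most of the gene (45705100 to 45710203). Its peaks held 451 to 850 reads each, at 12.1-fold to 13.9-fold enrichment, a value the authors' peak caller gave for each peak over its local background within 1 library. Read numbers below are likewise per called peak. Of the peaks assigned to Dbp, a fraction of 0.4 also lay in the span of the neighbouring gene Sphk2, so part of that signal cannot be assigned to either gene. The main region of Usp2, at 44090544 to 44095909 on chromosome 9, held 219 to 717 reads, and that of Noct, at 51224382 to 51233333 on chromosome 3, held 41 to 409. For Usp2, a fraction of 0.3 of the peaks also lay in the span of Gm39325.

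Of the 25 genes in the clock list, 20 had a peak in at least 1 library. The number with a peak was 3, 14 and 13 in the knockout libraries and 10, 14 and 15 in the wild-type libraries, or 10 ± 6.08 against 13 ± 2.65 (SD, n = 3, exact two-sided permutation p = 0.6). The 3 members called in wild-type libraries only compare with 0.349 expected from all genes with a peak (Fisher's exact test, p = 0.00478, Benjamini-Hochberg adjusted p = 0.172 over 36 tests), so the list did not pass the threshold. When every list was reduced to its 3023 strongest peaks, the length of the shortest list, 5 members were called in the wild-type libraries only (Fisher's exact test, adjusted p = 0.00137): Dbp, Usp2, Hlf, Nr1d1 and Per3. Noct then had a peak in 2 of the wild-type libraries, as it did with a score of at least 100 or a fold of at least 5. In the other direction, Cry2 and Rora each had a peak in 2 knockout libraries and no wild-type library with 3023 peaks per list. With 3023 peaks per list, members with a peak numbered 3.67 ± 0.577 in the knockout and 9.67 ± 1.15 in the wild-type libraries (SD, n = 3, exact p = 0.1, adjusted p = 0.36 over 18 lists). Without wild-type library 2, the adjusted p of the clock list was 0.0372, with 4 members, and under the other alternatives it ranged from 0.106 to 1 (0.817 with a fold of at least 5, 0.75 without wild-type library 1). In a permutation test that kept the list lengths, added afterwards, the clock list had z = -1.79 (p = 0.0949, adjusted p = 0.3 over 18 lists), and without knockout library 1 the difference in members turned from -3 to 0.5.

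**Figure D1:**
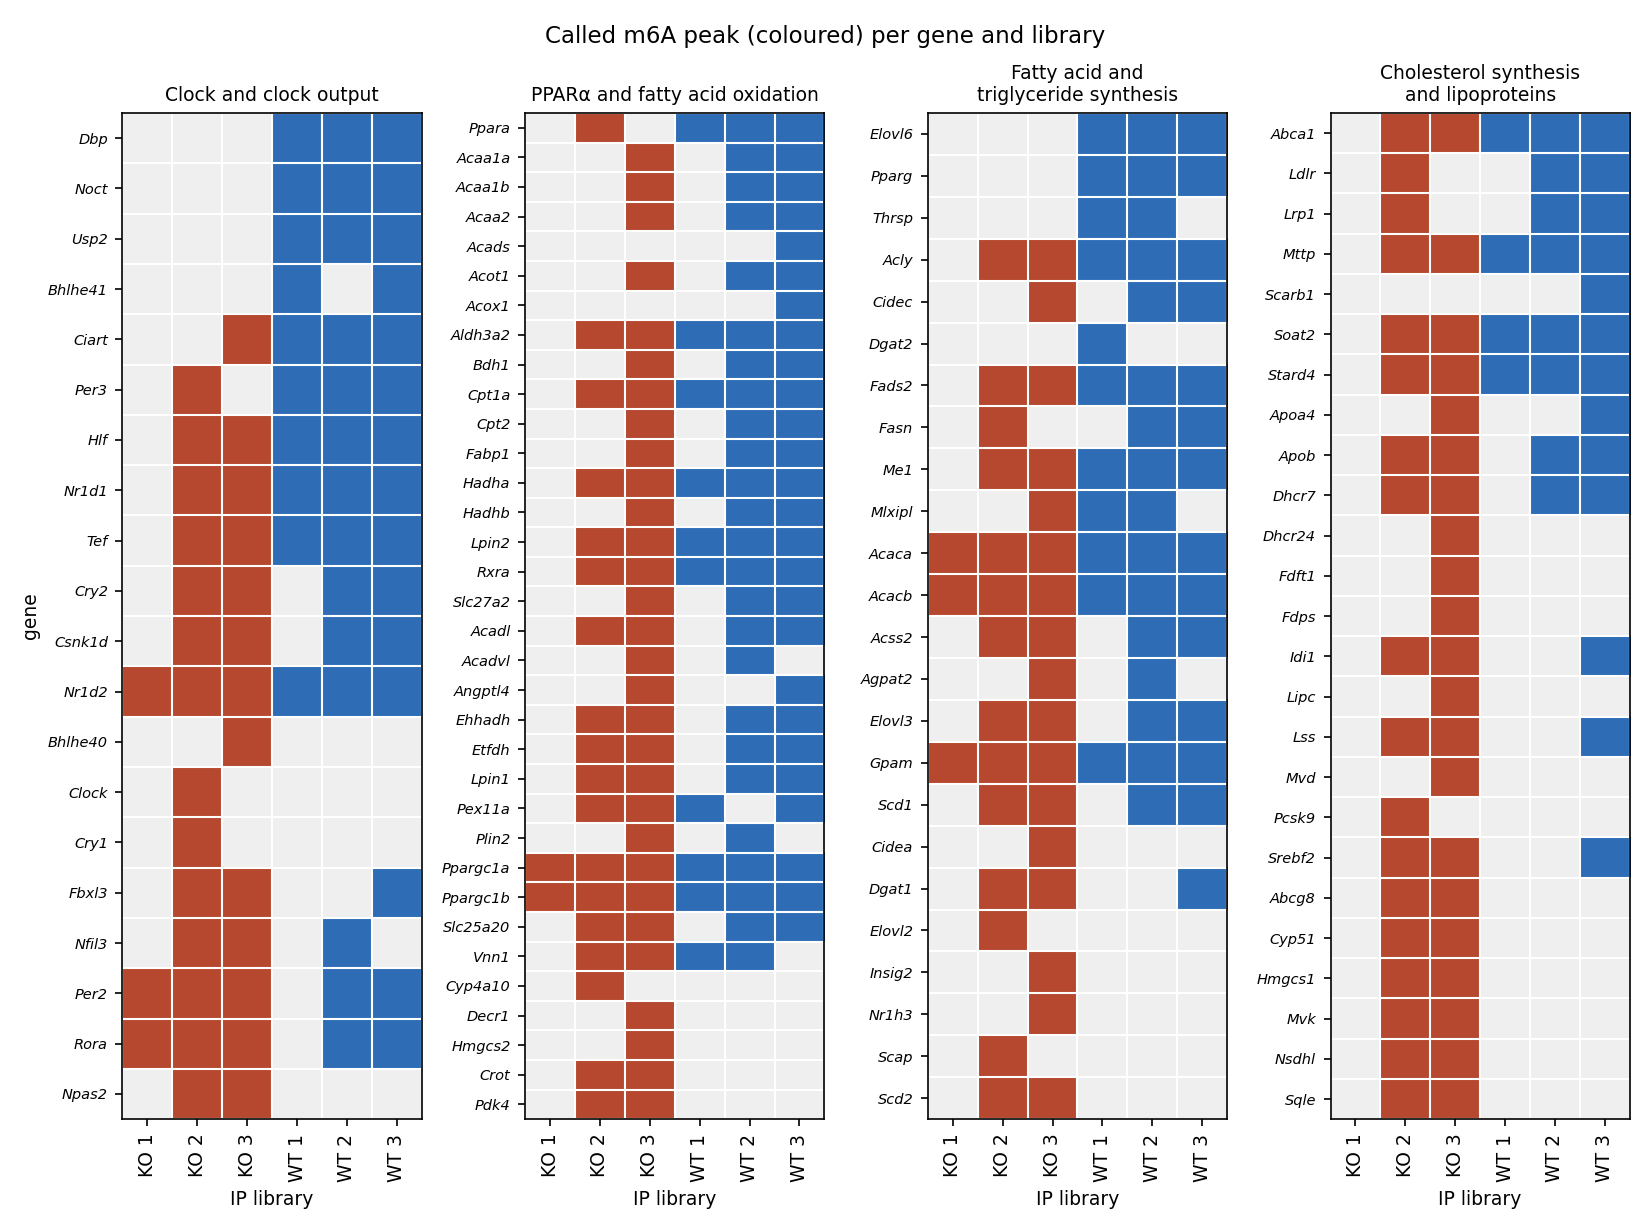
Called m6A peaks per gene (vertical axis) and immunoprecipitated library (horizontal axis) for members of 4 gene lists, chosen from those with a peak in at least 1 library; a coloured cell is a called peak (red in knockout, blue in wild-type libraries) and a grey cell is none. Dbp, Noct and Usp2 are coloured in the 3 wild-type libraries alone, and knockout library 1 has few coloured cells in every list.

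Over all genes, 182 had a peak in the 3 wild-type libraries and in no knockout library, and 90 had a peak in the 3 knockout libraries and in no wild-type library, out of 10440 genes with a peak in at least 1 library. The wild-type set held 4 genes of the Y chromosome: Ddx3y, Eif2s3y, Kdm5d and Uty, which had 29, 27 and 32 peaks between them in the wild-type libraries and 0 in each knockout library. It also held 14 major urinary protein (Mup) genes, a family of near-identical copies on chromosome 4. Reads cannot be placed reliably among such copies, so the 14 are not independent results. With the 14 Mup genes included, 38 of the 182 wild-type genes lay on chromosome 4, against 2 of the 90 knockout genes. The share of chromosome 4 among all genes with a peak is not given here, and the reason was not tested. By biotype, 139 of the 182 genes were protein-coding and 43 were long non-coding RNAs, against 80 and 10 of the 90 knockout genes.

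Ranked by the median within-list percentile of the authors' score, minus 10 times log10 of the peak's p-value, the leading wild-type genes were Cyp4a12a, Ddx3y, Cyp4a12b, Nat8, Col27a1, Gm52743, Gm33459, Zfp982, Nat8f5 and Slc2a5. Cyp4a12a encodes an arachidonic acid hydroxylase that is male-specific in adult mouse liver. Its main region (chromosome 4, 115331465 to 115332815) held 219 to 325 reads at 177-fold to 208-fold enrichment. Cyp4a12a and Cyp4a12b are near-identical copies and Nat8 and Nat8f5 are related neighbours, and peaks in either member of such a pair are uncertain. Col27a1 and Gm52743 overlap and share their main region (chromosome 4, 63332686 to 63335287). The region of Ddx3y (chromosome Y, 1260415 to 1264146) held 252 to 385 reads. Slc2a5, the fructose transporter GLUT5, had its main region at 150142654 to 150144349 on chromosome 4, with 85 to 151 reads.

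The leading knockout genes were Denn2b, Slc16a5, Sema6a, Cdkn1c, Srgap3, Atp11a, Plxna2, Dyrk3, Ikbip and Gm17746. Denn2b lies on the same chromosome as Arntl, at a distance of 3.47 Mb; its main region (chromosome 7, 109556073 to 109557970) held 210 to 471 reads at 3.49-fold to 6.78-fold enrichment. Cdkn1c, the imprinted inhibitor of cyclin-dependent kinases p57, was the only member of any list called in knockout libraries alone (chromosome 7, 143459689 to 143461109, 24 to 114 reads); with a score of at least 100 or a fold of at least 5 it had a peak in 2 of them.

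Chance sharing between lists of such unequal length gives many genes of this kind, so the counts were set against 500 randomisations that kept each gene's number of libraries and each library's number of genes. These gave 52.9 ± 7.1 wild-type genes (mean ± SD over randomisations), a ratio of 3.44 observed over expected, and 45.9 ± 6.47 knockout genes, a ratio of 1.96. Among the 20 sets of 3 libraries these were the highest and second highest ratios. Both randomisation p-values were 0.002, the smallest 500 randomisations can give; they compare these libraries and carry no spread between animals. In merged regions, 689 were called in the wild-type libraries alone (153 ± 11.5 expected, ratio 4.49) and 94 in the knockout libraries alone (73.4 ± 8.29 expected, ratio 1.28), out of 31758 regions; by ratio these ranked 1 and 6 among the 20 sets. Leaving out 1 library gave knockout ratios from 1.09 (without wild-type library 2) to 2.95 for genes and from 0.868 (without wild-type library 2) to 1.77 for regions, and wild-type ratios from 1.48 (without wild-type library 1) to 3.42 for genes and from 1.88 (without wild-type library 2) to 4.35 for regions. The knockout excess was lost with 3023 peaks per list, at 59 genes against 62.6 expected, while the wild-type count was 179 against 25.7 expected. Only 86 of those 179 genes, and 11 of those 59, were also in the sets from the full lists.

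**Figure D2:**
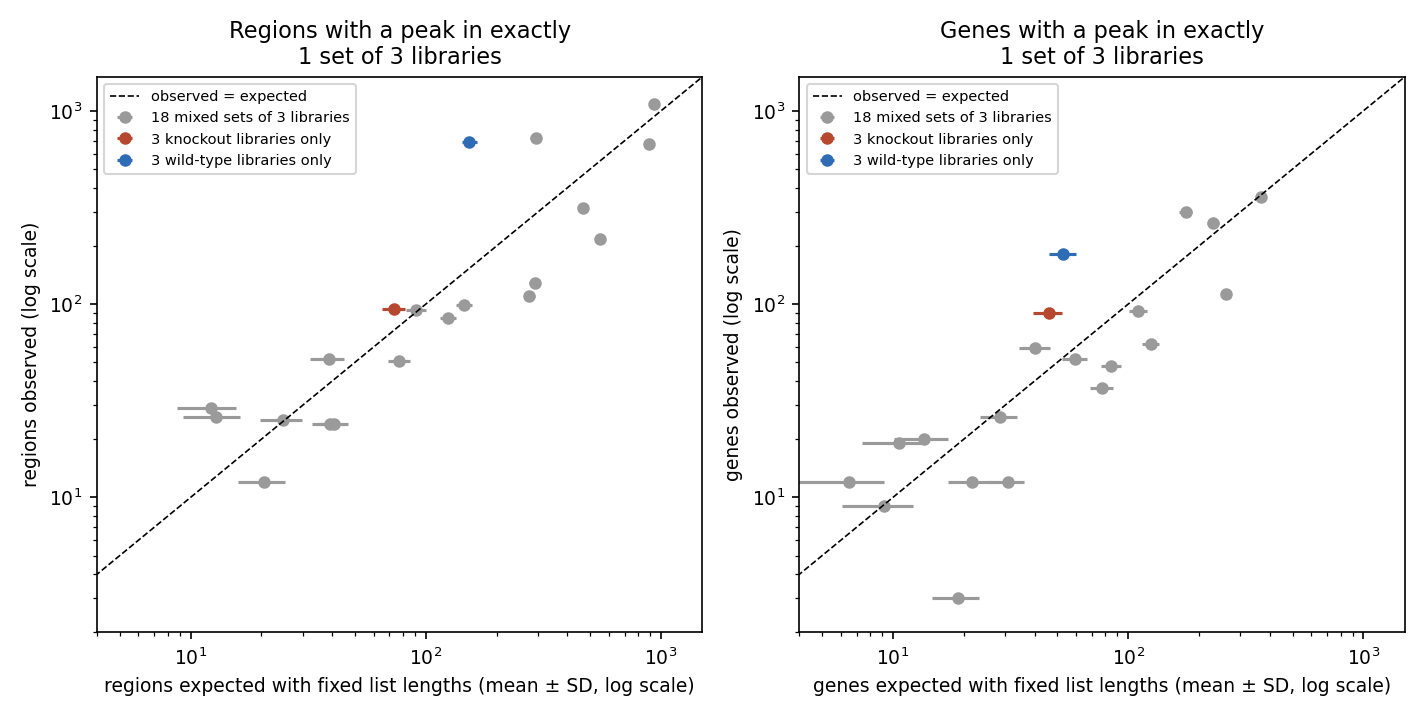
Regions (left) and genes (right) with a peak in exactly 1 set of 3 libraries: observed number (vertical axis, log scale) against the number expected with list lengths kept (horizontal axis, log scale, mean ± SD of 500 randomisations). Blue is the set of 3 wild-type libraries, red the set of 3 knockout libraries and grey the 18 mixed sets; the dashed line marks equality, and the wild-type set lies highest above it, at 689 regions and 182 genes.

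In the regulation and oxidation of fatty acids, Ppara, which encodes the nuclear receptor that switches on fatty acid oxidation in fasting liver, had a peak in all 3 wild-type libraries and in knockout library 2 only. The gene spans 85734910 to 85806851 on chromosome 15, and its main region (85735566 to 85739860) was called in 2 wild-type libraries and 1 knockout library, with 42 to 167 reads. Its peaks fell in 10 separate regions. Of the 39 genes in the list of PPARα targets and fatty acid oxidation, 34 had a peak somewhere: 2, 18 and 30 in the knockout libraries and 10, 25 and 26 in the wild-type libraries (16.7 ± 14 against 20.3 ± 8.96, SD, n = 3, exact p = 0.7). The coactivators Ppargc1a and Ppargc1b had a peak in all 6 libraries. Cpt1a, the carnitine palmitoyltransferase of the outer mitochondrial membrane, and Hadha had one in 3 wild-type and 2 knockout libraries. Pdk4 and Crot had one in 2 knockout libraries and no wild-type library. Of all 10440 genes with a peak, 1267 had the first of these patterns and 649 the second. No list member was called in 1 genotype alone. Without knockout library 1, the shortest list, the difference in members turned from -3.67 to 3.67.

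Among genes of fatty acid and triglyceride synthesis, Elovl6, a fatty acid elongase, and Pparg, the nuclear receptor of fat storage, had a peak in the 3 wild-type libraries and in no knockout library. The main region of Elovl6 (chromosome 3, 129532263 to 129533091) held 38 to 58 reads and that of Pparg (chromosome 6, 115472711 to 115473356) 45 to 74. The acetyl-CoA carboxylases Acaca and Acacb and the acyltransferase Gpam had a peak in all 6 libraries. Of 32 members 24 had a peak, with 3, 14 and 17 in the knockout and 11, 16 and 14 in the wild-type libraries (11.3 ± 7.37 against 13.7 ± 2.52, SD, n = 3, exact p = 0.9). The 2 members called in wild-type libraries only did not pass (Fisher's exact test, p = 0.0649, adjusted p = 1).

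In cholesterol synthesis and lipoproteins, more members had a peak in knockout libraries 2 and 3 than in any wild-type library, as was so over all genes (6914 and 6380 against at most 6120). Hmgcs1, Sqle, Mvk, Cyp51 and Nsdhl, enzymes of the sterol pathway, and the sterol transporter Abcg8 had a peak in knockout libraries 2 and 3 and in no wild-type library. The number of members with a peak was 0, 19 and 22 in the knockout and 4, 9 and 14 in the wild-type libraries, 13.7 ± 11.9 against 9 ± 5 (SD, n = 3, exact p = 0.6), out of 33 members. Leaving out 1 library moved the difference in members from 4.67 to between 0.5 (without knockout library 3) and 11.5 (without knockout library 1). In the added permutation test the knockout excess had z = 2.29 (p = 0.018, adjusted p = 0.162 over 18 lists) and did not pass; 4 of the 10 splits of the libraries into 3 and 3, the real one included, gave a z as far from 0, up to 3.96. Markers of stellate cells and fibroblasts had a peak for 2, 9 and 9 of 13 members in the knockout and 1, 2 and 5 in the wild-type libraries (exact p = 0.3). The same added permutation test gave them z = 2.98 (p = 0.004, adjusted p = 0.0719), against at most 2.34 in the other splits. Dcn, Des and Col1a2 had a peak in knockout libraries 2 and 3 only.

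For the remaining lists the lowest exact permutation p was 0.3, and adjusted over the 18 lists every exact permutation p was 1. Members with a peak in the 3 knockout and the 3 wild-type libraries numbered 0, 9 and 17 against 3, 11 and 13 for bile acid synthesis and transport (exact p = 1), where Cyp7a1, the rate-limiting enzyme, had a peak in 2 knockout and 3 wild-type libraries. For glucose and amino acid metabolism they were 2, 9 and 14 against 4, 12 and 14 (exact p = 0.8), and for xenobiotic metabolism 1, 6 and 20 against 5, 14 and 18 (exact p = 0.8). In that list Gstp1, a glutathione transferase with the close copy Gstp2, was called in wild-type libraries only (chromosome 19, 4035649 to 4038392, 392 to 510 reads). Secreted hepatocyte proteins gave 0, 3 and 11 against 1, 8 and 11 (exact p = 0.8), with the acute-phase gene Saa1, a near copy of Saa2, in wild-type libraries only; it had a peak in 2 of them with a score of at least 100 or a fold of at least 5, and in 1 with 3023 peaks per list. Fetal and postnatal growth genes gave 2, 9 and 11 against 3, 5 and 5 (exact p = 0.4), stress and unfolded protein response genes 5, 13 and 13 against 5, 13 and 12 (exact p = 1), and ribosomal protein genes 0, 0 and 17 against 0, 5 and 5 (exact p = 1). Knockout library 3 alone had a peak in 17 of the 18 ribosomal protein genes called anywhere.

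Among markers of other liver cells, Kupffer cell and macrophage genes had a peak for 1, 9 and 10 members in the knockout and 2, 4 and 10 in the wild-type libraries (exact p = 1), and endothelial genes for 3, 12 and 8 against 4, 5 and 8 (exact p = 0.7). Cholangiocyte genes gave 0, 4 and 2 against 1, 1 and 1 (exact p = 0.7), erythroid genes 1, 3 and 3 against 3, 3 and 3 (exact p = 1), and lymphocyte genes 1, 1 and 2 against 0, 1 and 0 (exact p = 0.3). With 3023 peaks per list, members with a peak numbered 5 ± 3.46 in the knockout against 1 ± 1 in the wild-type libraries for endothelial, 3.67 ± 2.08 against 0.333 ± 0.577 for stellate cell and 0.667 ± 0.577 against 2.33 ± 0.577 for erythroid genes (SD, n = 3, exact p = 0.1 each, the smallest possible, adjusted p = 0.36 over 18 lists). Kupffer cell genes then gave 3.67 ± 2.52 against 1 ± 1.73 (exact p = 0.2), and fetal and postnatal growth genes 3.33 ± 2.31 against 1 ± 0 (exact p = 0.1).

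Several transcripts of the m6A machinery were themselves called in both genotypes. Wtap, a subunit of the methyltransferase complex, the demethylase Fto and the reader genes Ythdf1, Ythdf2, Ythdf3 and Ythdc1 had a peak in all 6 libraries. The catalytic subunit Mettl3 had a peak in 1 wild-type library, its partner Mettl14 in 2, and the demethylase Alkbh5 in 1 of each genotype. The list gave 9, 15 and 10 members in the knockout and 11, 14 and 13 in the wild-type libraries (11.3 ± 3.21 against 12.7 ± 1.53, SD, n = 3, exact p = 0.7). The 6 members with a peak in every library compare with 1.64 expected (Fisher's exact test, p = 0.00405, adjusted p = 0.0728 over 18 lists). Without knockout library 3 the adjusted p was 0.0389, with 7 members, and under the other alternatives it ranged from 0.0536 to 1; with a score of at least 100, or 3023 peaks per list, 1 member was left.

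In all, 953 of the 10440 genes had a peak in every library and 2773 in only 1. Ranked by the median within-list percentile of the authors' fold enrichment, the leading genes common to the 6 lists were Acacb, Cib3, Pkn2, Xpc, Stard13, Fam13a, Eea1, Gbf1, Map2k6 and Rubcn. The main region of Acacb, which encodes the acetyl-CoA carboxylase that restrains fatty acid oxidation, lay at 114204479 to 114205250 on chromosome 5. It was called in all 6 libraries at 18.9-fold to 71.3-fold enrichment but held only 9 to 39 reads. Xpc, a DNA damage sensor, had its region at 91510345 to 91511221 on chromosome 6, with 16 to 44 reads.

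The number of peaks per list was 3023, 19510 and 10909 in the knockout and 7466, 11327 and 14527 in the wild-type libraries, 11147 ± 8246 against 11107 ± 3536 (SD, n = 3, exact two-sided permutation p = 1). Genes with a peak numbered 2440, 6914 and 6380 against 4028, 5409 and 6120, or 5245 ± 2444 against 5186 ± 1064 (SD, n = 3, exact p = 1). Covered length was 8766 ± 5960 kb against 9316 ± 2036 kb (SD, n = 3, exact p = 0.9), and the median peak width 615 ± 124 bases against 578 ± 87.6 bases (SD, n = 3, exact p = 0.6). With 3 libraries against 3, no such test can give a p below 0.1. Reads inside peaks ranged from 200269 in knockout library 1 to 1327283 in knockout library 2. The total reads sequenced are unknown here, so a peak missing from a short list may have been below detection.

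Overlap between peak lists was on average highest among the wild-type libraries. The Jaccard index, the shared bases over all covered bases, was 0.34 ± 0.0777 for the 3 wild-type pairs, 0.151 ± 0.051 for the 3 knockout pairs and 0.206 ± 0.069 for the 9 pairs between genotypes (mean ± SD over pairs, which share libraries). Lists of unequal covered length cannot overlap fully, which caps the index. Covered length ran from 3039 to 14935 kb in the knockout and from 7254 to 11324 kb in the wild-type libraries. The low knockout values therefore need not mean lower agreement. Pairs between genotypes ranged from 0.118 to 0.296, so that some exceeded the lowest wild-type pair, at 0.275. The mean within genotypes exceeded that between genotypes by 0.04, the highest of the 10 splits of the libraries into 3 and 3 (exact one-sided permutation p = 0.1, the smallest this statistic allows). Without wild-type library 1, 2 or 3 the difference was -0.00489, -0.0169 or 0.000503, and with a reciprocal overlap of 50% it was 0.0298 and no longer the highest (exact one-sided permutation p = 0.4).

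**Figure D3:**
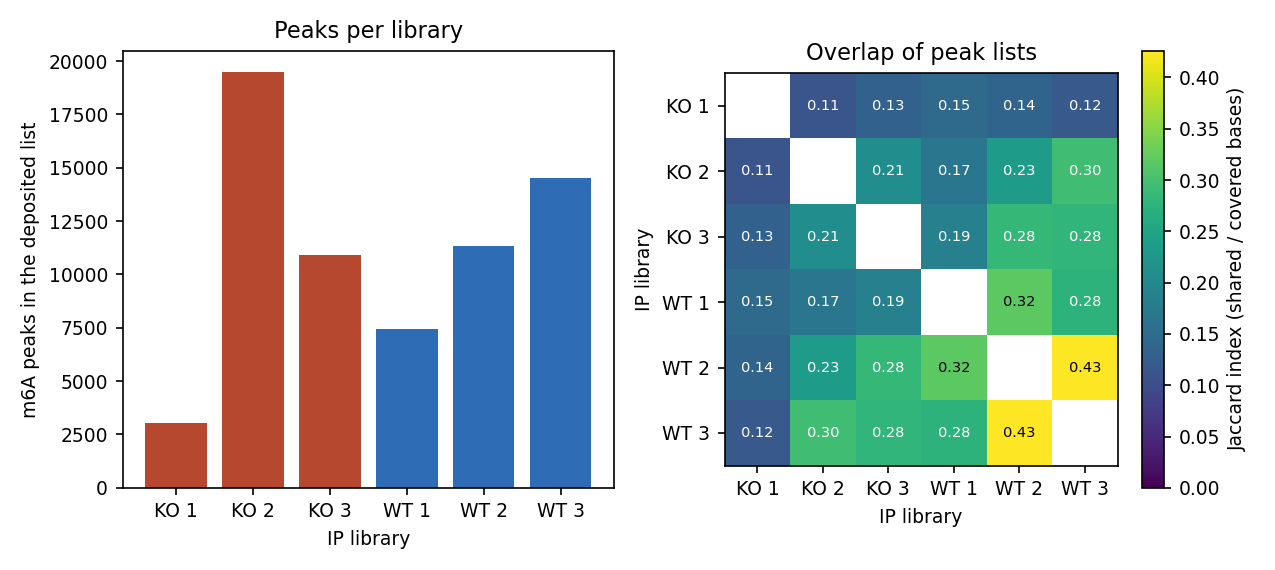
Left, number of m6A peaks in each deposited list (vertical axis) by immunoprecipitated library, red for knockout and blue for wild-type, from 3023 to 19510. Right, Jaccard index of covered bases for each pair of libraries; wild-type pairs lie between 0.275 and 0.426, knockout pairs between 0.112 and 0.209 and pairs between genotypes between 0.118 and 0.296.

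At least 95.2% of the peak summits in each list lay inside the annotated span of a protein-coding or long non-coding gene, and 4.14% to 5.56% lay in more than 1. In genes of at least 5000 bases, summits within 1000 bases of either end of the span made up 12.5%, 8.71% and 16.6% in the knockout and 9.92%, 10.1% and 10.1% in the wild-type libraries (exact p = 0.4). Random positions in the same genes gave 4.73% to 8.19%. This measure does not separate the start of a gene from its stop codon side. By the authors' false discovery rate, few peaks were at or below 5%: 1, 132 and 38 in the knockout and 0, 0 and 1 in the wild-type lists, with median rates from 11.2% to 46.9%. Every result above rests on peaks that passed the caller's p-value threshold but mostly not that rate.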

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

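The results without chromosomes X and Y were added after the data were examined. Alternatives planned for transcript parts and the sequence motif, motif windows included, were not run because exons and sequence were not used here. Differences are knockout minus wild-type means. With a score of at least 100, the difference in the number of peaks per library went from 40.7 to -174 and that in genes from 59 to -123. The counts of wild-type and knockout regions became 412 and 11, of knockout genes 13 and of genes in all libraries 56. Of the genes called in 1 genotype only, 93 of the 182 wild-type and 2 of the 90 knockout genes were kept. The list differences turned for m6A genes (0.333) and stress genes (-2), and for Per2 (1 more wild-type than knockout library). With a false discovery rate of at most 5%, too few peaks were left: regions and genes of either genotype, and genes in all libraries, numbered 0, and covered length differed by 148 kb instead of -550 kb. The lists for fatty acid synthesis (0.333), glucose metabolism (0.667) and xenobiotic metabolism (0.333) turned there. With a fold of at least 5, covered length differed by 217 kb, knockout regions numbered 50 (51.5 expected), genes in all libraries 506, and the list of secreted proteins turned (0.333). With 3023 peaks per list, the median width differed by -43 instead of 36.3 bases, wild-type and knockout regions numbered 384 and 47, knockout genes 59 and genes in all libraries 216. There 1 list, the clock genes, passed its threshold instead of 0, and the lists for m6A (1) and stress (-0.333) turned. With merged summits, knockout regions numbered 55 against 79.2 expected. Fewer peaks per list lower the number of genes in all libraries by construction; for the other shifts the cause was not tested.

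Leaving out 1 library at a time, the differences ranged from -4141 to 4103 peaks, -776 to 1461 genes, -3635 to 2313 kb of covered length, -33.8 to 84.2 bases of median width and -0.0169 to 0.0994 in Jaccard index. Wild-type and knockout regions numbered 724 to 1460 and 116 to 1092, wild-type and knockout genes 199 to 448 and 121 to 555, and genes in all libraries 986 to 1977; fewer libraries raise the gene counts by construction, and for the regions the cause was not tested. Lists past the threshold numbered 0 to 1, for genes of 1 genotype as for genes in all libraries. List differences that turned ranged from -5 to 0.5 for the clock, -10.3 to 3.67 for fatty acid oxidation, -5.17 to 1.83 for fatty acid synthesis, -4.5 to 4 for bile acids, -4.67 to 1.5 for glucose metabolism, -8.83 to 0.667 for xenobiotic metabolism and -5.17 to 0.333 for secreted proteins. They were -2.17 to 3 for stress genes, -0.167 to 4.33 for endothelial, -3.33 to 5.17 for ribosomal and -0.333 to 4.17 for Kupffer cell genes. Wild-type genes exceeded the expected number with each library left out, with ratios from 1.48 to 3.42, and without chromosomes X and Y (178 genes, 52.9 expected). Knockout genes had ratios from 1.09 (without wild-type library 2) to 2.95, and knockout regions from 0.868 to 1.77, below 1 without wild-type library 2 or 3.

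Whether the replicate numbers pair the samples stayed undecided. Deviations of same-numbered libraries correlated at 0.083, -0.0487 and 0.0138 over regions and 0.133, -0.0616 and 0.0114 over genes. Differently numbered libraries gave -0.0804 to 0.0697 over regions and -0.127 to 0.1 over genes. Knockout library 1 with wild-type library 1 was the highest in both, but so few pairs cannot exclude or show pairing. With the replicate number as a block, the differences were again 40.7 peaks (exact sign-flip p = 1) and 59 genes (exact p = 1). The 689 wild-type regions and 182 wild-type genes were the highest of the 8 flips (exact p = 0.125), and no call changed. Depth limits every absence: a gene without a peak in the list of 3023 may have been missed there.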

Other observations

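The tests chosen only after the results were seen were those of list length for both the Y-linked and the clock genes, the list of E-box genes, the male-biased list without Mup genes, and the counts relative to list length; the lists of sex-biased genes, the genes near Bmal1 and the plain counts over other splits were set before their results were seen.

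Genes known for sex-biased expression in adult mouse liver differed between the genotypes as groups. Of 30 male-biased genes, 2, 18 and 20 had a peak in the knockout and 21, 27 and 25 in the wild-type libraries. Mup3, Mup7 and Ugt2b38 and the peroxisomal hydrolase gene Nudt7 had one in all 3 wild-type libraries and in no knockout library, and Hsd3b5, a steroid dehydrogenase gene, in 3 and 1. Of 43 female-biased genes, 4, 16 and 22 had a peak in the knockout and 1, 3 and 10 in the wild-type libraries. Sult1e1, Sult2a2, Prlr, Cd36, Vldlr, Ntrk2 and Atp6v0d2 had a peak in knockout libraries 2 and 3 and in no wild-type library. These genes were named after their values were seen, and 5 of the male-biased and 6 of the female-biased genes also stood in a list of the report.

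The 4 Y-linked genes had peaks in wild-type libraries alone; shorter or weaker knockout lists are argued against, since at the wild-type rate the longest knockout list would hold 51.5 peaks in Ddx3y, Eif2s3y, Kdm5d and Uty and it held 0. The values are consistent with a hypothesis that the groups differed in sex: against randomisations that keep list lengths, the male-biased genes had z = -5.32 and the female-biased genes z = 4.31, with -3.84 for the male-biased list without Mup genes (leaving out 1 library, -5.06 to -4.03 and 2.68 to 4.6; highest sizes in the other splits, 3.23 and 3.18). Xist, the X-linked RNA that female cells express, had no peak in any library, knockout included, which does not go with female knockout animals, but neither had the nuclear RNAs Malat1 and Neat1, so its absence excludes nothing. The lists are of adult liver whereas the labels give postnatal day 21, so whether these genes differ by sex at the stated age, and whether that age holds, stays open. An effect of the knockout on sex-biased genes stays open as untested. These open points concern the sex-biased lists. They leave aside the 4 Y-linked genes, with 29, 27 and 32 peaks in the wild-type libraries and 0 in each knockout library. If the hypothesis holds, genotype and sex cannot be separated for any difference between the groups. That covers genes called in either genotype only, the clock genes and the gene lists alike.

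The clock output genes Dbp, Usp2 and Noct had peaks in wild-type libraries alone. Unequal list lengths alone are argued against for these 3 genes: randomisations that keep them gave 0.156 such genes of the clock list on average. For the 3 observed the randomisation p was 0.001, the smallest that 1000 can give. The excess was not particular to clock genes: over all genes, 182 were called in wild-type libraries only, against 52.9 expected. Set against all genes with a peak, 0.349 were expected and the clock list did not pass (Fisher's exact test, adjusted p = 0.172). Over all members of the clock list, the randomisations gave z = -1.79. Without knockout library 1, the difference in members with a peak turned from -3 to 0.5. Whether the genotypes were collected at the same time of day cannot be told, as the sample information used here holds no such time. A lower transcript level and a lower methylation per transcript in the knockout cannot be told apart, because transcript levels were not analysed here. The z of -4.24 over 13 genes activated through E-box elements decides nothing: the list was drawn from clock genes whose values had been seen, these 3 among them, and either would give it.

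Denn2b, called in knockout libraries alone, and Sox6os, called in wild-type libraries alone, lie within 10 Mb of Bmal1. A candidate explanation is DNA of another strain beside the targeted gene. Genes there were called in 1 genotype only in 2 of 89 cases (2.25%), against 270 of 10351 elsewhere (2.61%; odds ratio 0.858, Fisher's exact p = 1). With 2 such genes the test neither supports nor excludes an effect at single genes, and no biological explanation was tested.

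Over the 10 splits of the 6 libraries, regions of 1 genotype only (783) were matched or exceeded in 2 splits, the real one included, and the highest other split gave 1109, with knockout library 2 and wild-type libraries 2 and 3 on one side. Genes (272) were matched or exceeded in 4, with 372 as the highest other. Relative to the number expected from list lengths, the real split was the highest in both, 1 of 10: 3.45 against 2.34 for regions and 2.75 against 1.68 for genes. Too few splits exist for a share under 0.05.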
